A study of Macaca fascicularis with 24 samples.

How the data were processed

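Brain tissue tagged cortical region from cynomolgus monkeys was profiled by RNA sequencing on the Ion Proton platform. Total RNA was extracted with Trizol and libraries were made with the Ion RNA-Seq kit v2, per the labels' protocols. The aligner, the counting program, its use of strand, the gene annotation and the genome build are not given in the sources used here. The deposited tables hold whole-number counts per gene without normalization, per the file headers and the values themselves. The larger table has 35903 lines and 24 sample columns, and 6 of these columns stand identically in a smaller table. It also holds 4 columns named as averages, whose deposited counts are whole numbers near the sum of the named animal's 3 libraries (0.955 to 0.995 of it); they are called pooled columns and were used, as counts, only in checks and alternatives. No source states the unit of the pooled columns; the unit record first gave counts and now gives other, because it takes only 1 pooled count column per group and the wild-type group has 3.

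The columns of the 3 older transgenic animals and 1 pooled column were displaced against the gene names from line 4241 on, because 22 lines had dropped out of them. The places of the 22 lines were found by matching the displaced pooled column to the sum of its own animal's libraries. The columns of the older animals were then moved by the same places, on the assumption that the same lines were missing from them. The log2 correlation of that column with its summed libraries was 0.191 as deposited and 0.974 after realignment, and the median Spearman correlation of the displaced with the other libraries was 0.181 and 0.913. All 22 dropped lines and those of uncertain place were left out, 59 lines in all. In 5 simulated repeats of such a displacement, 2 to 5 lines were placed wrongly. Those repeats matched redrawn counts to the same sums. The real pooled column lay within 1.1-fold of its summed libraries for only 79.0% of genes compared, so the number placed wrongly in the real columns is not known. Of 21551 identifiers that the table gives as numbered loci, 3446 received a symbol from the RefSeq gene table of assembly T2T-MFA8v1.1, which was used for names and neighbouring genes only, and 12873 symbols of the table were found in it. A further 19 gene names had turned into dates.

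Animals were the replicates: libraries whose titles share a start were summed, which gave 12 animals, and the groups follow the genotype and age tags. Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and the quasi-likelihood F test, all 5 groups in 1 fit, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 22996 genes. The biological coefficient of variation was 0.462, with 7 residual degrees of freedom. A group of 1 animal was tested with the spread of the others. Levels are CPM computed from the deposited counts with TMM factors. Each comparison tested against the newborn wild-type animals or, for age within the transgenic animals, against the newborn transgenic animal. Single values were compared by exact permutation over animals.

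Gene groups were 27 lists, of which 26 had at least 3 measured genes. They cover cell types (excitatory, immature and inhibitory neurons, radial glia, astrocytes, oligodendrocytes and their precursors, microglia, endothelium), contaminating tissue (blood, choroid plexus, meninges, regions outside the cortex, X-inactivation and Y-linked genes), synapses (GABA, glutamate, vesicle release), state (proliferation, immediate early genes, hypoxia, heat shock, interferon, ribosome, respiratory chain) and disease (MeCP2-regulated genes, FMRP targets, autism risk). They were tested with limma 3.58.1's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 26 lists. List levels are means of log2 CPM with a prior count of 2. Named genes are MECP2 and FMR1, then the 8 largest rises and 8 largest falls among genes past the threshold that have a symbol, a mean of at least 5 CPM, and every library of the first group on the same side of the median of the second group's libraries, then up to 3 members of each described list with the smallest p. The comparisons, tests, lists, this rule and the first group of alternatives below were fixed before the data were examined.

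Alternatives fixed in advance were RLE size factors or library totals in place of TMM, DESeq2 1.42.0, no filter and a filter of 5 CPM in 3 animals, a minimum fold of 1.5, only the groups compared, libraries as replicates with and without a random animal effect or the number in the title as a block, only the smaller table, and each animal or library left out in turn. Chosen after seeing the data were the counting set as a term and only genes on which both countings lie within 1.1-fold. The pooled columns in place of the summed libraries (with and without the animal labelled MECP2 knockout) were added then too. So were no mitochondrial genes, only lines above the first displaced one, and the libraries with a title number without the block. The gene lists without FMR1 knockout animal Mfa009 were also added then.

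Library totals of 11708153 to 19201079 counts put the floor of 3 counts at 0.0561 to 0.237 CPM per animal. Simulated counts for 21740 genes with 200 genes changed per group were tested first. For 8-fold changes edgeR recovered 82% in the FMR1 knockout design, 44% and 39% in the newborn transgenic and MECP2 knockout designs with 1 animal, 84.8% in the older transgenic against wild-type design and 53.8% in the older against newborn transgenic design. For 2-fold changes it recovered 3%, 0%, 0%, 3.45% and 0%. With libraries as replicates, 69.7% to 95.3% of the calls were false, at an assumed dispersion of 0.02 between libraries of 1 animal. That value was not estimated from the data, where libraries of 1 animal had a consensus correlation of 0.580. The false share need not hold there. Intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Nothing was left out except the 59 lines, and no coordinates are given.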

Results

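RNA from brain tissue tagged cortical region in cynomolgus monkeys (Macaca fascicularis) was sequenced in 24 libraries from 12 animals, where libraries whose titles share a start were read as pieces of 1 animal. At the postnatal day 0 tag (P0) there were 10 libraries from 4 wild-type animals, 3 libraries from 1 MECP2 transgenic animal, 3 libraries from 1 animal labelled MECP2 knockout, and 5 libraries from 3 FMR1 knockout animals. A further 3 MECP2 transgenic animals carried a tag of 1 or 3 years and gave 1 library each. The source names call every animal an aborted newborn, so the groups follow the age tags. Library totals ranged from 11708153 to 19201079 counts. Mitochondrial mRNA took 0.993% to 5.77% of the counts in the wild-type libraries, 7.44% to 11.01% in those of the newborn transgenic animal, 1.32% to 8.11% in the FMR1 knockout, 0.903% to 1.88% in the animal labelled MECP2 knockout and 5.73% to 7.21% in the older transgenic animals. Values are CPM, counts scaled to a common library size, with the SD between animals.

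MECP2 encodes a protein that binds methylated DNA and is mutated in Rett syndrome; its duplication causes a separate neurodevelopmental disorder. Its mRNA stood at 59.4 ± 8.79 CPM (SD, n = 4) in the wild-type animals and at 57.8 ± 2.01 (SD, n = 3) in the FMR1 knockout animals. The newborn transgenic animal had 1253 CPM, 21.1 times the wild-type mean, and its 3 libraries had 1093, 1353 and 1427. The older transgenic animals had 232 ± 83.0 CPM (SD, n = 3), 3.90 times the wild-type mean, with 142, 305 and 249 in the individual animals. The animal labelled MECP2 knockout had 53.5 CPM, inside the range of the wild-type animals (50.2 to 71.4), and its libraries had 49.1 to 63.0, inside that of the wild-type libraries (47.8 to 74.2). The counts therefore did not separate that animal from wild type at MECP2, and a frameshift that leaves the mRNA in place would not show in them. FMR1 encodes FMRP, an RNA-binding protein that regulates translation at synapses. Its mRNA stood at 41.0 ± 5.76 CPM (SD, n = 4) in the wild-type animals and at 27.1 ± 7.31 (SD, n = 3) in the FMR1 knockout animals, whose values were 22.5, 35.5 and 23.2. Every FMR1 knockout animal lay below the lowest wild-type animal, which had 37.7, but the mRNA was present in each, and 1 lay above the newborn transgenic animal, so the counts did not show that FMRP was absent. FMR1 stood at 32.0 CPM in the newborn transgenic animal, 42.7 in the animal labelled MECP2 knockout and 36.2 ± 4.55 (SD, n = 3) in the older transgenic animals.

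**Figure D1:**
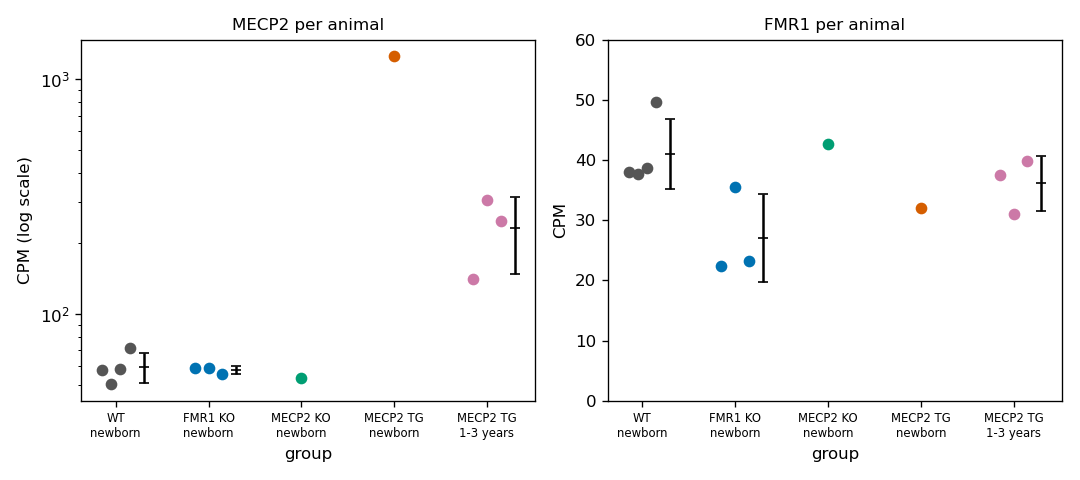
MECP2 (log axis) and FMR1 (linear axis) in CPM for each animal, by group; points are animals and bars are the group mean and SD. The newborn transgenic animal stands at 1253 CPM of MECP2 against a wild-type mean of 59.4, and the animal labelled MECP2 knockout at 53.5.

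Some genes appeared to have been counted differently in part of the libraries, although no source states this. For 602 genes the summed libraries of 3 animals held over 2 times the counts of the deposited pooled columns. These columns were read as a second count of the same animals' libraries. On these genes the libraries fell into 2 sets of 12, called counting sets here. The genes averaged 2.36 to 2.70 log2(CPM + 1) in the libraries of wild-type animals Mfa132 and MfaD02, the newborn transgenic animal and the animal labelled MECP2 knockout, and 0.501 to 0.694 in those of the other 8 animals. In the pooled columns of 3 of those 4 animals they were no higher than 0.585; the animal labelled MECP2 knockout has no pooled column and was not used to choose the genes. The countings gave values within 1.1-fold of each other for 79.0% of genes in the newborn transgenic animal and for 86.9% and 88.7% in the wild-type animals.

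**Figure D2:**
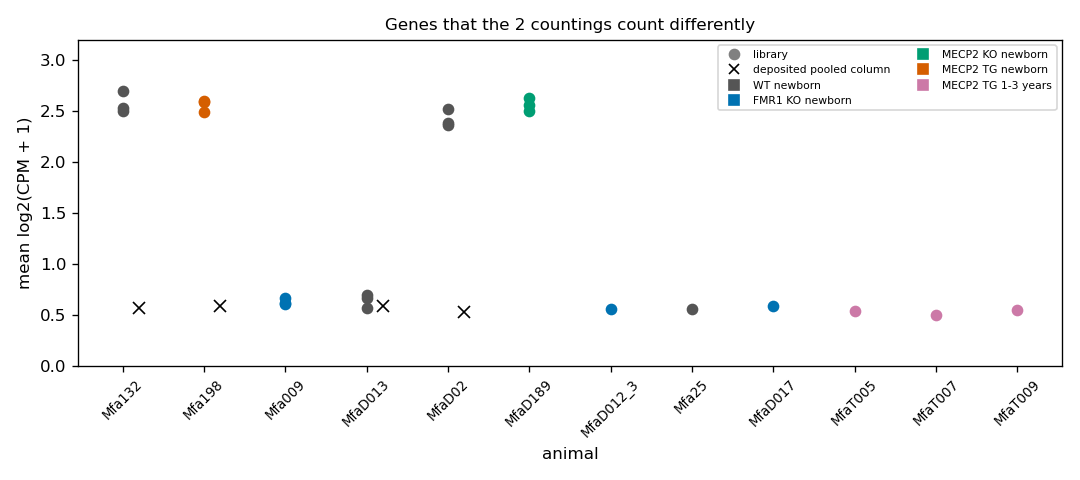
Mean log2(CPM + 1) of 602 genes in each of the 24 libraries, by animal; points are libraries and crosses are the deposited pooled columns. The libraries of 4 animals lie between 2.36 and 2.70 and all others at or below 0.694, while the pooled columns of the former lie at or below 0.585.

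The series describes itself as an examination of brain transcriptomes in wild-type and MECP2 transgenic monkeys, and the newborn transgenic animal against the newborn wild-type animals is its most direct comparison. MECP2 was the gene that rose, by 4.4 on the log2 scale (SE 0.33), in the only transgenic animal of that age. Genes of tissue outside the cortex and of the choroid plexus and ependyma, which make and move cerebrospinal fluid, were higher as groups. Genes of glutamate and GABA signalling, the hypoxia response and the respiratory chain were lower as groups by small amounts. None of these groups passed with an estimated correlation between genes. Of 22996 genes tested with edgeR's quasi-likelihood test, 1 passed, MECP2, with an adjusted p of 0.000372, and 140 had an unadjusted p under 0.05. On the counts of the deposited pooled columns 13 genes passed, 1 higher and 12 lower, and DESeq2 called 4.

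Of the 26 gene lists tested with camera, 6 shifted against other genes in the newborn transgenic animal, with 0 members past the threshold over all genes. The non-cortical region list (19 genes measured, 16 of them higher) had a camera adjusted p of 9.62e-05. Its mean log2 CPM ran from 2.14 to 4.13 between the 3 libraries of this animal, the lowest inside the range of the wild-type animals (1.42 to 2.88). Its member EN2, a transcription factor of the midbrain and hindbrain, was the only one past the threshold when adjusted over the list alone, with 1.82 CPM against 0.0501 ± 0.0572 (SD, n = 4). The choroid plexus and ependymal list (11 genes) had a median log2 change of 1.14 and a camera adjusted p of 0.000104. Its mean log2 CPM ran from 0.0915 to 4.54 between the 3 libraries of this animal and from 1.13 to 4.32 between those of wild-type animal MfaD013, so the rise depends on the library. Its member FOXJ1, a regulator of motile cilia, stood at 17.3 CPM against 7.61 ± 4.44 (SD, n = 4), and CCDC153 at 2.15 against 0.477. The 4 lower lists had medians of −0.24 (glutamate receptors and postsynaptic scaffold, 34 genes, camera adjusted p 0.0261), −0.34 (hypoxia response, 17 genes, 0.0279), −0.15 (nuclear-encoded respiratory chain, 75 genes, 0.0364) and −0.29 (GABA synthesis, transport and receptors, 20 genes, 0.0463). For all 6 lists camera gave an adjusted p of 0.811 with an estimated correlation. With the libraries' counting set as a term, 3 lists passed, 2 higher and 1 lower. The hypoxia and respiratory chain lists lay inside the wild-type range of mean log2 CPM, at 4.69 (4.43 to 5.51) and 5.10 (4.80 to 5.50). The transgenic group held 1 animal, which was assumed to vary like the others. By chance alone 1150 genes would lie at an unadjusted p under 0.05, more than were found here. The test of 1 animal was therefore cautious and could miss changes.

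The animal labelled MECP2 knockout was set against the same 4 wild-type animals to ask what changes in the absence of MeCP2; its MECP2 level gave no check of that label. No single gene passed, and differences lay in groups of genes. Fewer genes lay at an unadjusted p under 0.05 than the 1150 expected by chance. The test of 1 animal was therefore cautious and could miss changes. Ribosomal protein and respiratory chain genes were slightly higher and red blood cell genes were higher. Genes of the meninges, synapses, interferon response and regions outside the cortex were lower. None of these groups passed with an estimated correlation between genes. In edgeR's test 0 genes passed (259 with an unadjusted p under 0.05), DESeq2 called 2, and the smallest edgeR adjusted p was 1. Without wild-type animal Mfa132 the count was 2. With pooled columns in place of the summed libraries of the other animals it was 231, of which 230 were higher; this animal has no pooled column, so that fit compared it across the countings.

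Camera placed 10 lists past the threshold for the animal labelled MECP2 knockout, 3 higher and 7 lower, with 0 members of any list past the threshold over all genes or adjusted over the list alone. Nuclear-encoded respiratory chain genes had a median log2 change of 0.20 over 75 genes (camera adjusted p 0.000176) and cytosolic ribosomal protein genes 0.17 over 75 genes (0.00064). Both lists lay inside the wild-type range of mean log2 CPM, respiratory chain at 5.47 (4.80 to 5.50) and ribosomal at 6.13 (5.27 to 6.23). So did the non-cortical region list given below, at 1.82 (1.42 to 2.88). RPL15, a protein of the large ribosomal subunit, stood at 768 CPM against 441 ± 60.5 (SD, n = 4), and ATP5J, an ATP synthase subunit, at 74.6 against 39.7. Of 14 blood cell genes 11 were higher (camera adjusted p 0.00106), among them ALAS2, the first enzyme of haem synthesis in red cells, with 12.6 CPM against 3.22 ± 1.63 (SD, n = 4). The meningeal and fibroblast list had a median of −1.0 over 9 genes (camera adjusted p 0.000721), but its mean log2 CPM ran from 2.17 to 4.80 between the 3 libraries of this animal, and the highest lay inside the range of the wild-type animals (4.39 to 4.91). PTGDS, a prostaglandin synthase of the meninges, stood at 46.4 CPM against 217 ± 94.0 (SD, n = 4). The interferon response list had a median of −0.43 over 15 genes (camera adjusted p 0.00811), with MX1 at 3.21 CPM against 12.8. The mean log2 CPM of that list was 1.83, just below the wild-type range of 1.85 to 2.51. Between the 3 libraries of this animal it ran from 1.37 to 2.35. Lower lists of neuronal genes were glutamate receptors (−0.30, 34 genes, camera adjusted p 0.00106), FMRP and its mRNA targets (−0.36, 29 genes, 0.00176), GABA (−0.32, 20 genes, 0.00497) and synaptic vesicle release (−0.37, 21 genes, 0.00497). GRIN1, the obligatory NMDA receptor subunit, stood at 319 CPM against 633 ± 104 (SD, n = 4), and NOS1, the neuronal nitric oxide synthase, at 6.49 against 18.8. Of 19 non-cortical region genes 17 were lower (camera adjusted p 0.00205). With an estimated correlation, camera gave an adjusted p of 0.540 for the blood list and 0.866 for the other 9 lists.

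The FMR1 knockout animals were set against wild type at the same age tag to ask what changes with that label. In myelin genes they lay on both sides of wild type, and in genes of cell division and progenitors 1 animal lay far above the others. Animal Mfa009 had the lowest myelin genes of all 12 animals and the highest progenitor and proliferation genes, while the other 2 animals had the highest myelin genes among the newborns. Ribosomal protein genes were higher and GABA genes lower as groups, with or without Mfa009. For both lists camera's adjusted p was 0.457 with an estimated correlation. In each list 1 knockout animal other than Mfa009 lay inside the wild-type range of mean log2 CPM. It stood at 5.88 for ribosomal genes (wild type 5.27 to 6.23) and at 6.48 for GABA genes (6.34 to 6.65). FMR1 itself had a log2 change of −0.60 (SE 0.24), with an edgeR adjusted p of 0.505 over all genes and 0.0553 over the 2 target genes. A two-sided exact permutation test gave p = 0.0571, the smallest that 3 animals against 4 allow.

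In edgeR's test 0 genes passed in the FMR1 knockout comparison, with 2223 at an unadjusted p under 0.05, where 1150 would be expected by chance, and a smallest adjusted p of 0.499. DESeq2 called 161 genes, 56 higher and 105 lower; on simulated counts of this design, 31.9% of its calls were false against 8.60% of edgeR's. With the counting set as a term edgeR called 0 genes, with 878 at an unadjusted p under 0.05. Camera placed 12 lists past the threshold, 8 higher and 4 lower, with 0 members past it over all genes. Of 75 cytosolic ribosomal protein genes 73 were higher, with a median of 0.72 (camera adjusted p 7.92e-28) and of 0.38 without Mfa009. The GABA list had 19 of 20 genes lower, with a median of −0.51 (camera adjusted p 4.70e-07) and −0.33 without Mfa009. GAD1, which makes GABA from glutamate, stood at 119 ± 42.3 CPM (SD, n = 3) against 206 ± 14.9 (SD, n = 4), and SLC6A11, a GABA transporter of astrocytes, at 59.0 ± 29.6 against 139 ± 27.6. Adjusted over the list alone, 8 of 23 proliferation genes were higher (median 1.59, camera adjusted p 3.11e-10), but the median without Mfa009 was 0.20 and the list no longer passed. Likewise 7 of 16 radial glia and intermediate progenitor genes were higher when adjusted over the list alone (median 0.82, camera adjusted p 8.04e-07; 0.40 without Mfa009). SFRP1, a secreted Wnt inhibitor of cortical progenitors, had 252 CPM in Mfa009 and 77.0 and 93.8 in the other knockout animals, against 31.2 to 59.0 in wild type.

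Myelin and oligodendrocyte genes had a median log2 change of 1.89 in the FMR1 knockout animals (15 genes, camera adjusted p 0.00189). However, Mfa009 lay 4.22 below the wild-type mean of the list (−4.22 on the log2 scale). The other 2 knockout animals, with 1 library each, lay above every other newborn animal. Libraries of 1 animal also lay far apart in this list, by 4.14 on the log2 scale in wild-type animal Mfa132, whereas those of Mfa009 lay within 0.449; the labels do not name the piece of brain. Endothelial and mural cell genes were higher (median 0.52 over 18 genes, camera adjusted p 2.06e-05), as were hypoxia genes (0.32 over 17, 0.00222; 2 higher when adjusted over the list alone, HK2 and SLC2A1), respiratory chain genes (0.16 over 75, 0.00362) and meningeal genes (0.52 over 9, 0.0116). Glutamate receptor genes (−0.30 over 34, camera adjusted p 0.000188), synaptic vesicle genes (−0.27 over 21, 0.00175) and 17 of 19 non-cortical region genes (0.000348) were lower. For the respiratory chain, all 3 knockout animals lay inside the wild-type range of mean log2 CPM, at 5.22 to 5.48 (4.80 to 5.50). The same held for non-cortical region genes, at 1.504 to 1.78 (1.42 to 2.88). In hypoxia genes the knockout animals overlapped that range, at 4.93 to 5.53 (4.43 to 5.51). GRM5, the group I glutamate receptor studied with FMRP, stood at 137 ± 50.2 CPM (SD, n = 3) against 251 ± 56.5 (SD, n = 4). Without Mfa009 the glutamate, vesicle, proliferation and meningeal lists no longer passed, and the vesicle median was 0.10. The FMRP target list did not pass (median −0.12 over 29 genes, camera adjusted p 0.0845). Under an estimated correlation, camera's adjusted p lay between 0.457 and 0.710 for all 12 lists.

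**Figure D3:**
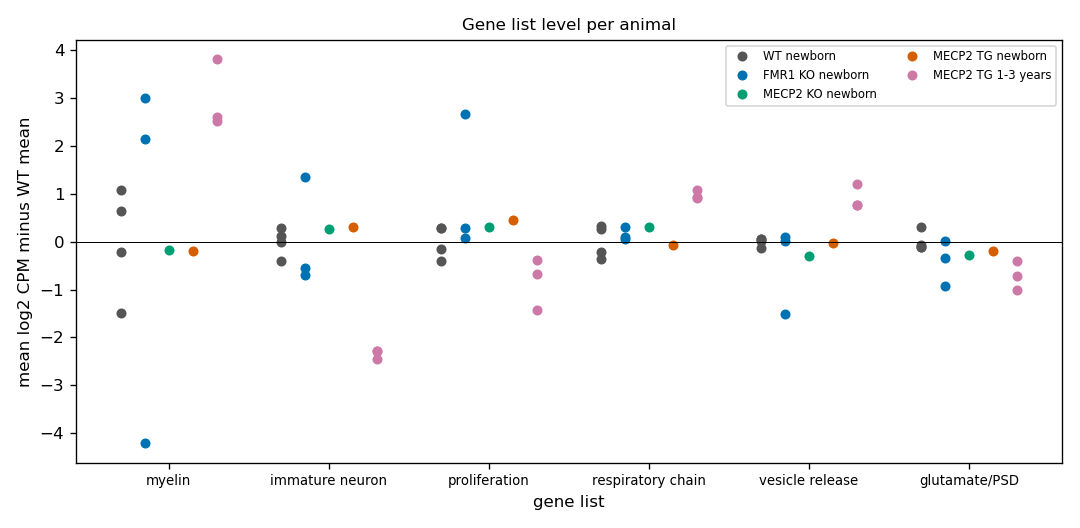
Level of 6 gene lists in each of the 12 animals, as mean log2 CPM minus the wild-type mean; points are animals, by group. FMR1 knockout animal Mfa009 lies at −4.22 in the myelin list, below all other animals. The 3 older transgenic animals lie together in the myelin and immature neuron lists, with an FMR1 knockout animal among them in the myelin list.

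The 3 transgenic animals of 1 to 3 years were set against the newborn wild-type animals, the only wild-type animals in the series. Age and genotype therefore changed together. The number of libraries differed too: 1 in each older animal and in wild-type animal Mfa25, and 3 in the other wild-type animals. Its effect was not tested. Respiratory chain, myelin, astrocyte, microglia and synaptic vesicle genes were higher as groups in the older animals, and genes of immature neurons, glutamate receptors and autism risk were lower as groups. None of these groups passed with an estimated correlation between genes. DPYSL3, a protein of growing axons, was at 105 ± 22.3 CPM (SD, n = 3) against 1897 ± 432 (SD, n = 4) in wild type. VAMP1, a vesicle fusion protein, was at 189 against 7.53 CPM, and CNDP1, which cleaves the dipeptide carnosine, at 198.2 ± 115 against 0.827 ± 0.449. GRIN2B, the NMDA receptor subunit that predominates early in development, was at 33.7 ± 19.4 against 287 ± 73.0 CPM. MECP2 rose by 1.96 on the log2 scale (SE 0.26, edgeR adjusted p 0.00111).

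Of 22996 genes 4573 changed between the older transgenic and the newborn wild-type animals, 2085 higher and 2488 lower (45.6% higher), by edgeR's quasi-likelihood test, and the median log2 change of all genes was −0.12. Scaled by library totals alone, 24.8% of 4952 genes were higher and that median was −0.41, so directions are relative to the scaling. All 3 older animals lay in 1 of the 2 counting sets with 2 of the 4 wild-type animals. With the set as a term 2146 genes passed, 2084 of them among the 4573. Leaving out 1 animal gave 2401 to 6609 genes, with 2401 without MfaT005, 2506 without MfaT007, 2611 without MfaT009, 2948 without wild-type animal Mfa132 and 6609 without FMR1 knockout animal Mfa009.

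Among the genes with the largest rises were CD74, the invariant chain of antigen presentation in microglia (log2 change 5.66, SE 0.53, edgeR adjusted p 0.000236; 246 ± 120 CPM against 4.80), and TNNT2, cardiac troponin T (5.87, SE 0.54; 93.7 ± 31.1 CPM against 1.54). CNDP1 rose by 7.89 (SE 0.90, edgeR adjusted p 0.000501) and DOCK5, a guanine nucleotide exchange factor, by 5.00. KCNS1, a potassium channel subunit, rose by 5.55, with 177 ± 142 CPM (SD, n = 3) against 3.78, and HAPLN2, a matrix link protein of nodes of Ranvier, by 5.37. S100A9, an alarmin of neutrophils and monocytes, rose by 6.0 but varied between animals (41.7 ± 62.7 CPM), and KLK6, a protease of oligodendrocytes, rose by 5.22. With the counting set as a term those last 2 had edgeR adjusted p values of 0.0572 and 0.0947 at log2 changes of 6.80 (SE 2.05, from 1.45) and 4.77 (SE 1.70, from 1.31), so the rises stayed and their error grew. POSTN, an extracellular matrix protein, fell by 7.06 on the log2 scale (SE 0.85, edgeR adjusted p 0.000604), from 33.0 ± 19.5 to 0.242 ± 0.216 CPM.

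The other 7 of the 8 largest falls lay in genes on which the countings differ. ASB14 had 0 counts in the older animals and was at least 115-fold lower, with a floor of 3 counts over the group. UGT2A1, SLC3A1, PKD2L2 and RFPL1 had 2 counts each in the older animals and were lower by 947-fold (exact Poisson 95% interval 262 to 7817), 584-fold (162 to 4823), 291-fold (80.7 to 2407) and 258-fold (71.5 to 2132). ULK4 stood at 7.49 ± 1.23 CPM (SD, n = 3) against 1527 ± 2970 (SD, n = 4), where wild-type animal Mfa132 alone had 5983. CYP2D6 stood at 0.263 against 35.4 CPM and kept an edgeR adjusted p of 0.00614 with the set as a term, at a log2 change of −3.33. With that term the other 6 no longer passed. SLC3A1 (edgeR adjusted p 0.496) went from a log2 change of −9.07 (SE 2.44) to −1.43 (SE 1.28), ULK4 (0.842) from −7.67 (SE 2.21) to −0.38 (SE 0.97), ASB14 (0.14) from −10.89 (SE 3.05) to −5.48 (SE 2.21) and UGT2A1 (0.0733) from −9.76 (SE 2.92) to −9.08 (SE 2.96), and PKD2L2 (0.285) and RFPL1 (0.401) turned to a log2 change of 3.57. UGT2A1 had 43.3 to 71.9 CPM in every animal with 3 libraries and at most 0.078 in every animal with 1 library, newborns included, and a log2 change of −0.74 with the pooled columns, so its fall was not specific to age or genotype. The Poisson intervals and floors cover counting error only.

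By cell type, 6 of 15 myelin and oligodendrocyte genes rose and 0 fell, or 12 adjusted over the list alone (median 2.88, camera adjusted p 9.64e-06). OPALIN, an oligodendrocyte membrane protein, stood at 154 against 5.27 CPM (log2 change 4.85), and ASPA, which frees acetate for myelin lipids, rose by 3.70. In the 4 wild-type animals the list's mean log2 CPM ran from 3.88 to 6.46, against 8.36 ± 0.72 (SD, n = 3) in the older animals. The newborn FMR1 knockout animals ran from 1.16 to 8.39 and the older animals from 7.91 to 9.19, so this level was not confined to the older animals. Astrocyte genes rose in 5 of 15 and fell in 0, also 5 adjusted over the list alone (median 1.08, camera adjusted p 0.00159), with the glutamine synthetase GLUL at 3271 against 643 CPM and the aldolase ALDOC at 2053 against 299. Microglia and macrophage genes rose in 5 of 15 and fell in 0, or 6 adjusted over the list alone (median 0.89, camera adjusted p 0.000885), with the complement gene C1QC at 209 against 36.6 CPM. Immature neuron genes fell in 8 of 13 and rose in 0 (median −2.22, camera adjusted p 2.94e-08); adjusted over the list alone, 11 fell and 1 rose. NREP, a neuronal regeneration protein, stood at 69.0 against 1000 CPM (log2 change −3.85), and STMN2, which regulates microtubules in growing axons, at 632 against 2566. DPYSL3 fell by 4.17 on the log2 scale (SE 0.42, edgeR adjusted p 0.000345). With an estimated correlation, camera gave an adjusted p of 0.534 for these 4 lists.

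Of 75 nuclear-encoded respiratory chain genes 46 rose and 0 fell (median 0.98, camera adjusted p 5.00e-19), or 55 higher and 1 lower adjusted over the list alone, among them NDUFS7 of complex I with 185 ± 22.7 CPM (SD, n = 3) against 56.3. Synaptic vesicle genes rose in 9 of 21 and fell in 1, or 9 and 2 adjusted over the list alone (median 0.66, camera adjusted p 0.00014), with VAMP1 up by 4.65 and the release regulator CPLX1 at 602 against 62.1 CPM. Glutamate receptor and postsynaptic scaffold genes fell in 12 of 34 and rose in 0, or 16 adjusted over the list alone (median −0.64, camera adjusted p 0.00014), with GRIN2B at a log2 change of −3.09, SHANK2 at −1.80 and GRM5 at −1.53. Autism risk genes fell in 14 of 33 and rose in 0, or 16 adjusted over the list alone (median −0.65, camera adjusted p 0.00014), with the transcription factor FOXP1 at −1.79 and ASXL3 at −2.99; GRIN2B is in both lists. Heat shock and unfolded protein genes rose in 5 of 16 (median 0.76, camera adjusted p 0.00157), with HSPB1 up by 1.73, and interferon response genes in 5 of 15, or 6 adjusted over the list alone (median 1.00, camera adjusted p 0.00585), with BST2 up by 2.52. Immediate early genes had 1 of 19 past the threshold, ATF3, on which the countings differ (median 1.87, camera adjusted p 0.00278), and non-cortical region genes 4 of 19 higher (camera adjusted p 0.00585), with DDC, an enzyme of dopamine and serotonin synthesis, up by 4.17. Single animals carried part of these rises, in mean log2 CPM. In immediate early genes MfaT009 stood at 7.41 and the other 2 at 4.28 and 4.46, inside the wild-type range of 3.05 to 4.79. In non-cortical region genes MfaT005 stood at 5.16 and the other 2 at 2.79 and 2.85, inside the wild-type range of 1.42 to 2.88, and DDC in MfaT007 (0.779 CPM) lay inside its wild-type range. In interferon genes MfaT009 at 2.30 lay inside the wild-type range of 1.85 to 2.51. In these 4 lists 0 genes fell, and the counts adjusted over the list alone were 5, 6, 1 and 4. With an estimated correlation, camera gave an adjusted p of 0.534 for these lists, except 0.619 for immediate early genes.

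The remaining 14 lists did not pass camera's test in the older animals against wild type, although single members did. Of 14 blood genes 2 rose and 3 fell (camera adjusted p 0.165): SLC4A1, the anion exchanger of red cells, had 0 counts and was at least 19.3-fold lower, ALAS2 had 2 counts and was 73.1-fold lower (exact Poisson 95% interval 20.2 to 604), and S100A8, an alarmin, was higher at 10.2 ± 16.3 CPM. Meningeal genes had 1 of 9 higher, PTGDS with 1987 against 217 CPM, and 4 lower, with the collagen COL1A1 at 4.11 against 47.6 CPM (camera adjusted p 0.165). Interneuron genes had 1 of 20 higher, PVALB, the calcium buffer of fast-spiking cells, with 47.0 against 1.77 CPM, and 3 lower (camera adjusted p 0.688). GABA genes rose in 4 of 20 (camera adjusted p 0.281), with GABRD at 142 against 21.3 CPM, and excitatory neuron genes in 2 of 20 with 4 lower (0.236), with SATB2 at 32.2 against 193 CPM. Genes reported as MeCP2-regulated rose in 4 of 25 and fell in 1 (camera adjusted p 0.309); FKBP5, a glucocorticoid response gene, was up by 3.65, and MEF2C, a neuronal transcription factor, stood at 237 against 1397 CPM. FMRP and its targets rose in 3 of 29 and fell in 7 (camera adjusted p 0.688), with KCNC1, a channel of fast-spiking neurons, at 91.6 against 20.02 CPM. Radial glia genes rose in 3 of 16 and fell in 1 (camera adjusted p 0.992), with TNC, a matrix protein of outer radial glia, at 44.3 against 379 CPM. Hypoxia genes rose in 3 of 17 and fell in 1 (camera adjusted p 0.109), with NDRG1, also a myelin gene, at 770 against 208 CPM. The counts higher and lower were 0 and 2 of 23 for proliferation (camera adjusted p 0.281; MKI67 1.13 against 12.3 CPM), 3 and 1 of 18 for endothelial (0.374), 2 and 3 of 75 for ribosomal (0.309), 2 and 1 of 10 for oligodendrocyte precursor (0.908) and 1 and 0 of 11 for choroid plexus genes (0.0987). Adjusted over the list alone, the counts of these lists were the same except for excitatory neuron (2 higher and 6 lower), radial glia (3 and 2), oligodendrocyte precursor (2 and 2), blood (3 and 4), choroid plexus (0 and 0), hypoxia (3 and 2), ribosomal (1 and 3) and FMRP target genes (5 and 7). The X-inactivation and Y-linked list had fewer than 3 measured genes and has no result.

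Older and newborn transgenic animals were compared to follow age within 1 genotype label, with 3 animals against 1. Genes of immature neurons and the meninges were lower as groups in the older animals, and respiratory chain, myelin and heat shock genes were higher as groups, the last 2 with 0 members past the threshold. None of these groups passed with an estimated correlation between genes. MECP2 itself fell by 2.43 on the log2 scale (SE 0.36, edgeR adjusted p 0.00607), from 1253 to 232 CPM. CD24, a surface protein of young neurons, stood at 15.4 against 533 CPM, and CRYAB, a small heat shock protein, at 1140 ± 293 (SD, n = 3) against 49.7. DRAXIN, an axon guidance protein of development, was at 0.367 against 30.5 CPM.

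By edgeR 912 genes changed between the older and the newborn transgenic animals, 150 higher and 762 lower (16.4% higher), while 45.4% of the 2881 genes called by DESeq2 and 36.5% of the 2044 called with only the groups compared were higher; in edgeR's test 5613 had an unadjusted p under 0.05. With the counting set as a term, 43 genes passed, 3 higher and 40 lower, and MECP2 had an edgeR adjusted p of 0.108 at a log2 change of −2.50 (SE 0.55, from 0.36), so its fall stayed as large and its error grew; of the genes with the largest changes TNNT2, VEPH1 and POSTN still passed, each at 0.0477. The newborn transgenic animal and the 3 older animals lay in different counting sets, and gave 3 libraries and 1 library each. Without Mfa009, an animal outside the comparison, 2675 genes passed, and without MfaT007, MfaT009, MfaT005 or wild-type animal MfaD02 there were 278, 312, 320 and 584. Rises included HAPLN4, a matrix protein of perineuronal nets (log2 change 4.37, SE 0.76, edgeR adjusted p 0.0115; 179 against 8.66 CPM), SCN1B, a sodium channel subunit (306 against 10.2 CPM), MT1X, a metallothionein (34.6 against 1.37 CPM), and again CNDP1, CD74 and TNNT2. Falls included VEPH1 (log2 change −7.03, SE 0.79, edgeR adjusted p 0.00192; 0.106 against 14.8 CPM), POSTN (−6.91) and DRAXIN (−6.34). The remaining rise, EPN3, and the falls CYP2D6, SLC26A10, BRICD5, MXD3 and GJD3 are genes on which the countings differ.

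Camera placed 15 lists past the threshold between the older and the newborn transgenic animals, 10 higher and 5 lower. Immature neuron genes fell in 7 of 13, or 11 adjusted over the list alone (median −2.19, camera adjusted p 7.30e-10), with DPYSL3 at a log2 change of −4.23 and NREP at −3.55. Respiratory chain genes rose in 3 of 75, or 33 adjusted over the list alone (median 1.14, camera adjusted p 2.53e-17). Hypoxia genes rose in 3 of 17, also 3 adjusted over the list alone with 1 lower (median 0.62, camera adjusted p 0.0134), with NDRG1 up by 2.21, the glucose transporter SLC2A1 by 2.00 and PGK1 of glycolysis by 1.55. Lists with 1 gene higher were synaptic vesicle release (VAMP1; median 0.89, camera adjusted p 0.000627) and microglia (CD74; median 0.89, 0.0134); adjusted over the list alone, 2 and 1 were higher. Myelin (median 3.30, camera adjusted p 0.000108), heat shock (0.93, 0.00114), astrocyte (1.25, 0.00256), immediate early (1.84, 0.00353), interferon (1.61, 0.00383) and GABA genes (0.49, 0.0493) were higher as lists with 0 members past the threshold over all genes, and 4 interferon genes were higher adjusted over the list alone. The size of the immediate early rise came mostly from MfaT009 (mean log2 CPM 7.41), while the other older animals had 4.28 and 4.46 against 3.78 in the newborn. Lower lists were autism risk (3 of 33 genes: FOXP1, GRIN2B and ASXL3; camera adjusted p 0.0134), meningeal (2 of 9: COL1A1 and COL3A1; 0.0311), glutamate receptors (1 of 34: GRIN2B; 0.0338) and blood (3 of 14: ALAS2, SLC4A1 and GYPA; 0.0445), or 8, 4, 7 and 4 adjusted over the list alone. With an estimated correlation, camera's adjusted p lay between 0.506 and 0.680 for all 15 lists.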

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

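Tests chosen only after their result had been seen were those of genotype, counting set and spread between libraries for the FMR1 knockout animals, of genotype and of a second counting for the 602 genes, and of genotype, variation between libraries and ND3 for the ND4 ratio.

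Of 56 group values checked, 6 had a wild-type animal far from the other 3, and chance alone gives about 1 in 20. FMR1 stood at 49.7 CPM in wild-type animal Mfa25 against 37.7 to 38.7 in the others. CNDP1 stood at 1.49 CPM in MfaD013 against 0.542 to 0.694. UGT2A1 had 0 CPM in Mfa25, where 3 counts would be 0.208 CPM, against 51.7 to 61.3. ULK4 stood at 5983 CPM in Mfa132 against 6.52 to 104. The glutamate receptor list had a mean log2 CPM of 7.51 in Mfa25 against 7.08 to 7.12, and the meningeal list 4.39 in MfaD02 against 4.84 to 4.91. The effect of the MECP2 transgene label on MECP2 differed between the age tags: the log2 change at 1 to 3 years minus that at P0 was −2.43, with an edgeR adjusted p of 0.00607, and 0.108 with the counting set as a term (log2 change −2.50). These are different animals, 1 of them at P0, and the older ones alone ran from 142 to 305 CPM, so age and animal are not separated.

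The 3 FMR1 knockout animals lay apart along myelin, proliferation and progenitor genes. Mfa009 had a myelin level of −4.22 from the wild-type mean and another 3.01 (log2), which argues against the FMR1 genotype alone as the source for myelin genes. The 2 animals above wild type gave 1 library each, and libraries of 1 wild-type animal lay as far as 4.14 apart. A genotype effect beneath such a spread between libraries is therefore not excluded. In proliferation and progenitor genes all 3 lay above the wild-type mean, the lowest by 0.0860 and 0.0968 and Mfa009 by 2.67 and 1.38, so the genotype stays open there. The counting set is argued against too, since all 3 lie in 1 counting set, but this covers only those 2 sets. UGT2A1 counts also parted animals with 3 libraries, as Mfa009, from animals with 1, as the other 2. Other differences in processing between these animals were not tested. Different developmental stages may account for the spread of the 3 animals. MBP stood at 13.02 CPM and TOP2A at 150 in Mfa009, genes chosen after their values were seen. Across genes, the difference of Mfa009 from wild type had a correlation of −0.210 with the change to 1 to 3 years. In the other knockout animals it was 0.494 and 0.403. These values met what had been written for this explanation, but the wild-type animals ran from −0.198 to 0.511 on the same axis, so they were judged afterwards to leave stages and other differences between animals undecided; they cannot be told apart here. Differences of the size found between pieces of 1 animal are argued against for the proliferation genes of Mfa009, whose lowest library lay 1.97 (log2) above the highest of the other newborns, while libraries of 1 newborn ranged over at most 0.511. For its myelin genes they cannot be told apart from other sources, since its libraries lay within 0.449 but only 0.747 below the lowest other newborn library, and libraries of 1 animal ranged over as much as 4.14. A different region sampled in all 3 pieces stays open and untested.

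For the 602 genes, 2 of the 4 animals were wild type, which argues against genotype, and the pooled columns of 3 of them stood at 0.585 or below, the level of the other animals' libraries. The genes had been chosen for being lower in those columns, so a fall was built in, but not its extent nor the high level in the fourth animal. A counting without regard to strand in these libraries is a candidate explanation: ND6, the mitochondrial mRNA on the opposite strand to the other 12, moved by −3.50 or more in each of the 3 animals (−3.50 to −5.44 on the log2 scale), and the others by at most −0.0861. Reads of abundant neighbours were tested too, and 47.0% of the genes had a neighbour at least 10 times as abundant. Random draws had a mean of 37.2% and a 95th percentile of 41.1%, so the value met what had been written for this explanation. It was left undecided because only 47.7% of the genes could be placed. No biological explanation other than genotype was tested.

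The ratio of ND4 to COX1 counts differed between animals, with a log2 ratio of −3.80 in wild-type animal Mfa132, −3.34 in the animal labelled MECP2 knockout and −0.494 in the newborn transgenic animal. Its range among wild-type animals alone was 2.67, which argues against genotype, and the pooled column of Mfa132 lay within 0.00967 of its libraries, which argues against the counting set. Variation between libraries is undecided on ND4, where the SD within animals was 0.437 of that between animals. On ND3, which was looked at because of that outcome and had the widest range between animals among mitochondrial mRNAs, it was 0.0933. This argues against it for ND3 only: ND3 had 13 to 50 counts in each library of Mfa132 and the animal labelled MECP2 knockout and at least 3589 elsewhere. The log2 ratio of ND4 to COX1 itself ran from −4.57 to −3.44 between libraries of Mfa132 and from −4.51 to −2.93 in the animal labelled MECP2 knockout. A mitochondrial sequence shared by these 2 animals that differs from the reference stays possible and was not tested.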

How the results depend on the processing

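The counting set as a term, the genes on which the countings lie within 1.1-fold and the pooled columns were chosen after seeing the data. So were the lines above the first displaced one, no mitochondrial genes and the libraries with a title number without the block. The same holds for the list counts without Mfa009 and the correlation with wild-type animals of the same counting set. The other results were planned. The cause was not tested where none is named.

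For the FMR1 knockout, edgeR's count of 0 became 161 with DESeq2, 4284 with libraries as replicates, 5043 with the title number as a block and 6122 for the same libraries without it. The newborn transgenic count of 1 became 4 with DESeq2, 14 with libraries, 3 with a random animal effect, 3 with the block, 15 without it, 61 in the smaller table (2 animals, 1 per group, libraries as replicates), 13 with pooled columns and 12 with these and no knockout-labelled animal. For the animal labelled MECP2 knockout, 0 became 2, 49, 1 and 68 with DESeq2, libraries, block and no block, and 231 with pooled columns, where its own counting meets another. For the older transgenic animals against wild type, 4573 became 2202 at a minimum fold of 1.5, 8373 with libraries, 2146 with the set term and 462 above the displaced line, where fewer genes were tested. Against the newborn transgenic animal, 912 became 2881 (DESeq2), 419 (fold of 1.5), 2044 (only the groups compared), 7269 (libraries), 3134 (random effect), 43 (set term) and 69 (above the displaced line). In simulated data most calls with libraries as replicates were false, at an assumed dispersion of 0.02 between libraries of 1 animal. The false share in the real data is not known.

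Without each animal or library in turn the counts ran from 0 to 0 (FMR1 knockout), 1 to 1 (newborn transgenic), 0 to 2 (knockout-labelled, 2 without Mfa132), 2401 to 6609 (without MfaT005 and Mfa009) and 278 to 2675 (without MfaT007 and Mfa009). Lists past camera's threshold without Mfa009 were 14, 8, 11, 12 and 15 in the order FMR1 knockout, newborn transgenic, knockout-labelled, older against wild type and older against newborn, from 12, 6, 10, 12 and 15. With an estimated correlation they were 0, 0, 0, 0 and 0; with fry 0, 0, 0, 4 and 0. The newborn transgenic lists were 3 with libraries, 3 with the set term and 3 with pooled columns, and the knockout-labelled lists 5 with pooled columns.

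PKD2L2 turned from a fall to a log2 change of 3.57 with the set term and 1.06 with pooled columns, and RFPL1 to 3.57 and 3.55. Of 35 named calls 10 passed in the same direction in every alternative, 2 turned, and 1 of 7 named results not called was called in some. The correlation of MECP2 knockout-labelled and newborn transgenic effects (0.398) was 0.110 with separate wild-type animals (0.000952 in simulations without effects), 0.0961 with those of the same counting set (0.335), 0.204 over genes on which the countings lie within 1.1-fold (0.215) and −0.0367 with both the first and the last (0.00108).

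Title numbers did not pair libraries across all animals: 29 pairs with the same number had a median residual correlation of −0.022 (9 over 0.1) and 106 others −0.005 (28 over 0.1). Seen afterwards, the 6 pairs numbered 3 among Mfa132, Mfa198, MfaD013 and MfaD189 had 0.225 to 0.464, so a shared position in part of the animals is not excluded; block values stand here only. No paired analysis was possible for the older animals because their titles carry no number. Depth limits genes near the floors of 0.0561 to 0.237 CPM; with 1 or 3 animals per group, 2-fold changes were rarely recovered in simulated data.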

Other observations

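Tests chosen after the result had been seen were the counting set as a source of the shared effects of the 2 MECP2 animals and the alternatives restricted to genes on which both countings lie within 1.1-fold.

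Within the newborns, markers of the choroid plexus and of glia ran widely between animals of 1 genotype label. TTR, the transport protein made by the choroid plexus, stood between 0.277 and 242 CPM in the wild-type animals and at 400 CPM in FMR1 knockout animal Mfa009, and MBP of myelin between 300 and 2936 CPM in wild type. DCX, a microtubule protein of migrating neurons, stood at 1209 CPM in Mfa009 and 131 to 550 in the other newborns, while SNAP25 of mature synapses stood at 163 against 408 to 675. In the older animals DCX stood at 13.003 to 16.2 CPM and SNAP25 at 1820 to 2702. These 4 genes were chosen after their values were seen.

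Lists could differ in sign between median, mean and test where they did not pass. In the FMR1 knockout this held for excitatory neuron (median 0.16, test lower), immature neuron (median −0.06, mean 0.41), astrocyte (−0.05, mean 0.03) and autism risk genes (0.06, mean −0.09). In the older animals against wild type it held for radial glia (median −0.28, test higher) and FMRP target genes (−0.04, mean 0.17), against the newborn transgenic animal for endothelial (−0.18, test higher), choroid plexus (−0.24, test higher) and oligodendrocyte precursor genes (−0.01, mean 0.04), and for the animal labelled MECP2 knockout in astrocyte (0.08, mean −0.04) and microglia genes (−0.12, mean 0.00417).

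Other splits of the animals were tested where both groups held 3 or more. For the older transgenic animals against wild type, 1 of the 35 splits of the 7 animals, the real one, gave 4573 genes. The highest other gave 5. This argues against chance in grouping for that count, although 1 of 35 is the least that this test can give. The splits do not part age, genotype and the number of libraries per animal, which was 1 in every older animal. For the 12 lists of the same comparison, 13 of 35 splits gave as many and the highest gave 18, so chance is not excluded for their number. For the FMR1 knockout count of 0 genes the splits decide nothing, since all 35 of 35 must give as many (the highest other gave 7). There 6 of 35 gave as many as 2223 genes at an unadjusted p under 0.05, up to 2609, and 27 of 35 gave as many as 12 lists, up to 18; chance is not excluded for either.

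The effects of the MECP2 transgene and of the MECP2 knockout label, each against the same wild-type animals, correlated across 23491 genes with r = 0.398, where genes are not independent replicates. Simulated animals without any effect gave 0.213 because the controls are shared. With the wild-type animals in separate pairs the covariance averaged 0.0749, above the 0.0155 that simulations reached, as had been written for a source other than shared controls. The 6 pairings ran from −0.0460 to 0.230, with 2 below 0, so that rule was judged afterwards not to decide. Over 19040 genes on which the countings lie within 1.1-fold the covariance averaged −0.0252 and ran from −0.101 to 0.0769. Shared controls and the counting set that both animals share cannot be told apart here, because 4 wild-type animals give pairings that go both ways. Over the genes on which the countings lie within 1.1-fold, the correlation was 0.204, inside the simulated range of 0.192 to 0.236. With wild-type animals of the same counting set it was 0.0961, below the lowest simulated value of 0.315. No excess over the simulations remained over the genes on which the countings lie within 1.1-fold. The value with same-set controls lay below every simulated one, so those simulations did not describe these controls and decide nothing. Whether the 2 animals shared a response to a changed MeCP2 dose is therefore not settled. Such a response was not tested on its own, and the knockout label was not borne out by MECP2 counts.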
